A study of Mus musculus with 122 samples.

How the data were processed

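Per the labels, RNA came from the liver, small intestine, kidney, calf muscle and brain of 6-week-old male FVB mice. The mice were fed (0 h) or went without food for 12, 24, 48 or 72 h, and the same mice gave all 5 organs. Per the labels' protocols, total RNA was extracted with TRIzol and purified on RNeasy columns, and the mice used in each group were picked for the best RNA quality across the 5 organs. The RNA was amplified as amino allyl aRNA, coupled to a fluorescent dye and hybridized to printed spotted slides together with 1 common reference. The reference mixed every sample's RNA in equal parts, together with RNA of further mice that were given a vitamin B complex during 48 h without food. Those mice are not analysed here. The clock time at which the mice were killed, the scanner and the image software are not given in the sources used here.

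Each deposited array file holds, per the file headers, spot and local background values as intensity on a linear scale for the green and the red image, and the authors applied no normalization to them. The signal-to-noise ratio of each spot, a score per the file headers, and the percent of each spot's pixels at the scanner's ceiling, also per the file headers, were read from the same files. The table that the authors deposited holds normalized log2 ratios of each sample against the reference. Limma is named in the submitters' processing notes, and its steps and version are not given in the sources used here.

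The labels contradict each other on the dyes: the channel fields put the sample in Cy3, and the labelling protocol puts it in Cy5. The values settled this. The variance between tissues was 0.378 in the green channel and 0.00598 in the red channel. Marker genes of each organ were 3.80 to 6.09 log2 units higher in the green channel of that organ than in the other organs, against -0.02 to 0.49 in the red channel. Green (Cy3) was therefore read as the sample and red (Cy5) as the reference in all 122 arrays. The deposited log2 ratios matched the recomputed ones with a median correlation of 0.987 and a median slope of 1.05 across spots, and for 122 of 122 arrays the best match was the array's own column.

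Each array had 22680 spots in 24 print blocks. The annotation gave 1 gene symbol for 16076 of them, several for 288 and none for 6316, and the distinct symbols numbered 14442. The background was corrected with normexp (offset 50), and the log2 ratios were normalized within each array with global loess in limma 3.58.1 under R 4.3.3. The files were read with version 1.17.8 of data.table. A probe was tested in a tissue where its green signal-to-noise ratio was at least 3 on at least 3 arrays of at least 1 time group. For genes with several probes, the probe with the highest mean signal stood for the gene. This left 11774 genes in liver, 12218 in intestine, 11764 in kidney, 11021 in muscle and 11354 in brain.

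One linear model per tissue was fitted with limma over the 5 times, each group was compared with 0 h, and 72 h was compared with 24 h. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. A change is the difference between group means of the log2 ratio, so that 1 unit is a doubling, and ± gives the moderated standard error from limma unless SD is written. Differences of the response between tissues were tested with a moderated F test in 1 model over the 25 groups, on the 9702 genes tested in all 5 tissues. Gene lists fixed in advance were tested with camera in limma at the preset inter-gene correlation of 0.01, wherever at least 5 members were tested in the tissue. The same tests were run with a correlation estimated for each list and with ranks. The adjusted p of a list covers all 1076 tests of lists, tissues and comparisons. Where a list had 2 counts of changed members, the first was adjusted over all genes tested and the other was adjusted over the list alone.

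The comparisons, the gene lists, the main settings and the alternatives were chosen before the data were examined. The rule for named genes was also fixed then. It took the 5 largest rises and the 5 largest falls in each tissue at 24 and 72 h, among genes with an adjusted p under 0.05 whose fasted arrays all lay outside the range of the 0 h arrays. Clone and predicted-gene names were left out. Across tissues it took the genes changed in 1 direction in all 5 tissues. Members of the fixed lists and cell type markers are named whether changed or not. Every other gene named, and the members of lists given as examples, were chosen after their values were seen, and examples whose call held without any 1 array were preferred.

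The alternatives were no background correction, a normexp offset of 10, print-tip loess, median centring, between-array quantile normalization of the mean signal and the authors' value table. Others were array quality weights, a variance trend with robust estimation, no filter on dim probes, all probes of a gene, genes detected in any tissue, a fold change of at least 2, all tissues in 1 model, the slide family as a term, the mouse as a block and each array left out in turn. Scaling the arrays to 1 spread, scaling them to 1 slope on the mean of their tissue, and leaving out arrays with a quality weight under 0.2 were added after seeing the data. The slides fell into 6 families by a code in their file headers. That these families are print batches was inferred from the codes and is not stated in the labels.

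Because the labels give the same mice in all tissues, the deviations of arrays from their group means were compared between tissues. The median correlation was 0.0411 over the 238 same-mouse pairs of arrays, with 81 pairs above 0.1, against -0.0105 for arrays of different mice. The same mouse served as a block only in models that joined tissues. No mouse was measured at more than 1 time, so that no pairing exists within a tissue.

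The steps were tested on simulated data with the mean signals of the 0 h arrays and the residual spread of each spot. A change of 1 log2 unit was recovered for 57.5% of genes in liver, 48.0% in intestine, 59.5% in kidney, 60.5% in muscle and 60.5% in brain, with 3.04 to 6.69% of calls false. Estimates of such changes had a median of 0.548 to 0.635 of the true size, and 0.845 to 0.960 for spots with a signal of at least 500, so that the changes of dim genes were understated. In the test across tissues 15 of 101 calls (14.9%) were false, and 7 of 90 (7.78%) with 1 spread per gene in all tissues. Each share came from 1 run, and they were not tested against each other. Camera called a simulated list shifted by 0.5 (adjusted p = 6.35e-24) and 0 of the other 54. Simulated genes varied independently in every step, so that false calls from array-wide effects were not tested.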

Results

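The data were 122 arrays from 25 mice. Each of the 25 groups of tissue and fasting time held 5 arrays, except liver at 12 h, kidney at 24 h and brain at 24 h with 4. The share of spots with a signal above background had a median of 53.32% in liver (range over arrays 31.79 to 85.06%), 63.01% in intestine (46.24 to 96.80%), 65.43% in kidney (47.61 to 85.97%), 57.67% in muscle (32.27 to 78.00%) and 60.43% in brain (46.88 to 91.90%). Each comparison asked which transcripts of an organ differed after a given time without food from those of fed mice (0 h), and the comparison between organs asked whether the responses differed. All changes are log2 values against 0 h with standard errors from limma. For each gene in the lists of largest changes, every fasted array lay outside the range of the 0 h arrays. The plot of genes changed over time gives the size of each response.

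**Figure D1:**
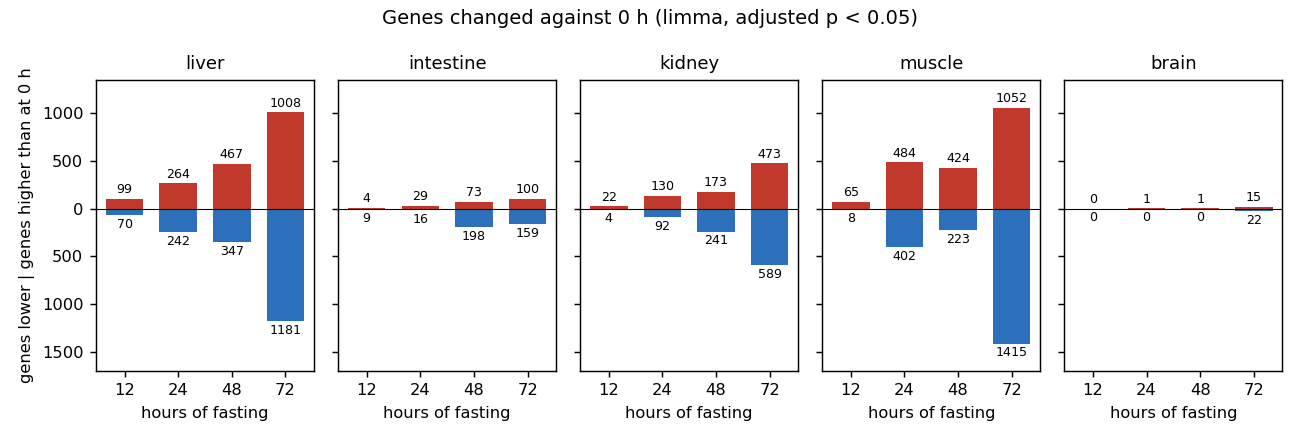
Number of genes changed against 0 h (limma, adjusted p under 0.05) in each tissue at 12, 24, 48 and 72 h of fasting; red bars count genes that were higher and blue bars genes that were lower. At 72 h the counts were 1008 and 1181 in liver, 1052 and 1415 in muscle, and 15 and 22 in brain.

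After 24 h without food the largest rises in liver were those of the fatty acid omega-hydroxylases Cyp4a14 and Cyp4a10, by 5.79 ± 0.42 and 5.58 ± 0.28 (5 fasted and 5 fed mice; adjusted p = 1.69e-08 and 4.7e-11). Cyp4a14 (gene identifier 13119, chromosome 4) went from a log2 ratio to the reference of -3.35 ± 0.49 (SD) in fed mice to 2.43 ± 0.36 (SD). The lipoprotein gene Apoa4 (3.55 ± 0.19), the metal-binding protein gene Mt1 (2.91 ± 0.42) and the lactate dehydrogenase gene Ldhb (2.65 ± 0.26) followed. The largest falls were those of the carbonic anhydrase Car3 (-3.21 ± 0.28), the aldehyde oxidase Aox3 (-2.36 ± 0.22), the sterol oxidase Msmo1 (-2.34 ± 0.36), the methyltransferase Inmt (-2.26 ± 0.27) and Nat8f1 (-2.15 ± 0.19). In total 264 genes rose and 242 fell among 11774, and 44 and 43 of these changed by at least 2-fold.

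Genes of fat use rose together in liver at 24 h. Among 21 measured genes of mitochondrial and peroxisomal fatty acid oxidation, 13 rose and 0 fell (15 and 0 adjusted over the list alone), with a median change of 0.48 (camera, adjusted p = 9.65e-19; adjusted p = 0.0564 with an estimated correlation). Ehhadh (1.14 ± 0.28), Eci1 (0.97 ± 0.11) and Acadm (0.61 ± 0.13) were among them, whereas the transport gene Cpt1a (-0.03 ± 0.080) did not pass the test. Of 18 PPAR alpha targets, a group of genes driven by a receptor for fatty acids, 7 rose and 0 fell (adjusted p = 1.56e-09; adjusted p = 0.0888 with an estimated correlation). Acot1 (1.51 ± 0.36), Ucp3 (1.07 ± 0.11) and Slc25a20 (0.45 ± 0.092) were among them. The calls of Ehhadh (0.97) and Acot1 (1.33) ended with slide family as a term. In gluconeogenesis, 4 of 13 genes rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 5.13e-05, and 0.03 with an estimated correlation): Got1 (2.13 ± 0.37), Pck1 (1.07 ± 0.16), Slc37a4 (0.84 ± 0.12) and Pcx (0.82 ± 0.10). Of 27 genes of the urea cycle and amino acid breakdown, 10 rose and 2 fell (adjusted p = 4.04e-08; adjusted p = 0.0903 with an estimated correlation). Oat (1.33 ± 0.24), Aass (1.11 ± 0.12) and Arg1 (0.79 ± 0.15) rose, and Otc (-0.68 ± 0.11) and Glud1 (-0.36 ± 0.077) fell.

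Sterol genes fell in liver at 24 h. Of 17 measured genes of cholesterol synthesis, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.52 (adjusted p = 2.4e-23, and 0.03 with an estimated correlation). Fdps (-2.02 ± 0.25), Insig1 (-1.42 ± 0.15), Idi1 (-1.26 ± 0.21) and Sqle (-1.09 ± 0.18) were among them, beside Msmo1. Of 21 genes of fatty acid and triglyceride synthesis, 4 fell and 2 rose (median -0.21, adjusted p = 0.00191; adjusted p = 0.146 with an estimated correlation). Acly (-1.25 ± 0.14), which makes acetyl-CoA for lipid synthesis, and the citrate carrier Slc25a1 (-0.54 ± 0.074) fell, whereas the spot for the fatty acid synthase Fasn rose by 2.43 ± 0.22, against the direction of most of its list. Of 11 genes of the growth hormone and IGF axis 2 rose and 2 fell (adjusted p = 0.664), among them the receptor Ghr (-0.91 ± 0.14), Igfals (-0.87 ± 0.21) and Igfbp2 (1.16 ± 0.15), and the call of Igfals (-0.84) ended with slide family as a term.

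At 72 h, 1008 genes were higher and 1181 lower in liver than at 0 h (5 mice each), 61 and 117 of them by at least 2-fold. Cyp4a14 (4.98 ± 0.42), Cyp4a10 (4.71 ± 0.28), Apoa4 (3.42 ± 0.19), Mt1 (2.66 ± 0.42) and the oestrogen sulphotransferase Sult1e1 (2.61 ± 0.32) rose most. The spot of Sult1e1 was not well above background at 0 h, so that the size of its rise is uncertain. In the green channel alone, open to dye bias, the rise was at least 6.37-fold (log2 means 7.81 and 10.51). The largest falls were those of Nudt7 (-3.58 ± 0.36), a peroxisomal hydrolase of coenzyme A, Car3 (-3.36 ± 0.28), the globin gene Hbb-b2 (-2.68 ± 0.20), Msmo1 (-2.67 ± 0.36) and Aox3 (-2.65 ± 0.22). Cholesterol synthesis had 14 of 17 genes lower and 0 higher (median -0.74, adjusted p = 7.06e-12; adjusted p = 0.106 with an estimated correlation). In fatty acid and triglyceride synthesis 12 of 21 genes fell and 1, Fasn, rose (1.94 ± 0.22; list adjusted p = 7e-04, and 0.106 with an estimated correlation). Elovl5 (-1.63 ± 0.27) and Acly (-1.51 ± 0.14) were lowest. Of the fatty acid oxidation genes 9 rose and 1, Acaa1a (-0.57 ± 0.17), fell (median 0.29, adjusted p = 7.09e-06; adjusted p = 0.365 with an estimated correlation). The call was lost for Acaa1a without mouse 1 or 6 at 0 h or mouse 35 or 36 at 72 h (-0.56 to -0.52). That of mitochondrial and peroxisomal fatty acid oxidation ended when the arrays were scaled to 1 spread (median 0.05, adjusted p = 0.328).

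Sex-dependent genes changed in liver at 72 h. Of 14 measured genes that are higher in male than in female mouse liver, 11 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.95 (adjusted p = 3.37e-08; adjusted p = 0.0564 with an estimated correlation). Besides Nudt7, they included the complement gene C6 (-2.46 ± 0.20), Gstp1 (-2.17 ± 0.23) and the oxysterol hydroxylase Cyp7b1 (-1.85 ± 0.31). Of 17 female-biased liver genes, 8 rose and 4 fell (adjusted p = 0.0183; adjusted p = 0.229 with an estimated correlation). Cyp17a1 (2.20 ± 0.21) and Fmo1 (1.19 ± 0.11) were higher and Cyp2c40 (-1.58 ± 0.27) lower. Ghr (-1.34 ± 0.14) was lower too. In the urea cycle and amino acid breakdown 14 of 27 genes rose and 0 fell (adjusted p = 2.15e-06; adjusted p = 0.156 with an estimated correlation), among them Cps1 (1.30 ± 0.20) and Aass (0.98 ± 0.12), and the call of this list ended with the arrays scaled to 1 spread (median 0.02, adjusted p = 0.253). Lists of other cell types were lower in liver too. Markers of the exocrine pancreas had medians of -1.60, -0.97, -1.36 and -1.43 at 12, 24, 48 and 72 h (adjusted p = 0.0388 at 72 h; adjusted p = 0.706 with an estimated correlation), and their 72 h call ended with slide family as a term (median -1.23, adjusted p = 0.101) and with the arrays scaled to 1 spread (median -1.54, adjusted p = 0.144) or 1 slope (median -1.41, adjusted p = 0.0535). Markers of macrophages and antigen presentation had 6 of 16 lower and 1 higher (median -0.35, adjusted p = 0.00672; adjusted p = 0.571 with an estimated correlation).

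The response of the liver had begun by 12 h, when 99 genes rose and 70 fell (4 fasted and 5 fed mice), or 109 and 143 with the arrays scaled to 1 slope. Cyp4a14 (4.53) and Cyp4a10 (4.60) were already higher, 5 of 21 fatty acid oxidation genes rose (14 adjusted over the list alone; adjusted p = 2.02e-14; adjusted p = 0.0851 with an estimated correlation), and 6 of 17 cholesterol synthesis genes fell (13 adjusted over the list alone; adjusted p = 8.26e-10; adjusted p = 0.164 with an estimated correlation). At 48 h 467 genes rose and 347 fell, with 14 of 21 fatty acid oxidation genes higher (adjusted p = 8.59e-19; adjusted p = 0.0564 with an estimated correlation) and 14 of 17 cholesterol synthesis genes lower (adjusted p = 6.23e-17; adjusted p = 0.0564 with an estimated correlation). Between 24 and 72 h, 318 genes rose and 358 fell, with Hbb-b2 (-2.24 ± 0.20), C6 (-2.00 ± 0.20) and Nudt7 (-1.79 ± 0.36) lower and Cyp17a1 (1.33 ± 0.21) higher. Without mouse 14 at 12 h the count at 12 h was 97 in place of 169. The difference between 72 and 24 h took counts of 389 to 438 without mouse 20 or 21 at 24 h or mouse 35 or 36 at 72 h, and 1731 without mouse 38 at 72 h, in place of 676.

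**Figure D2:**
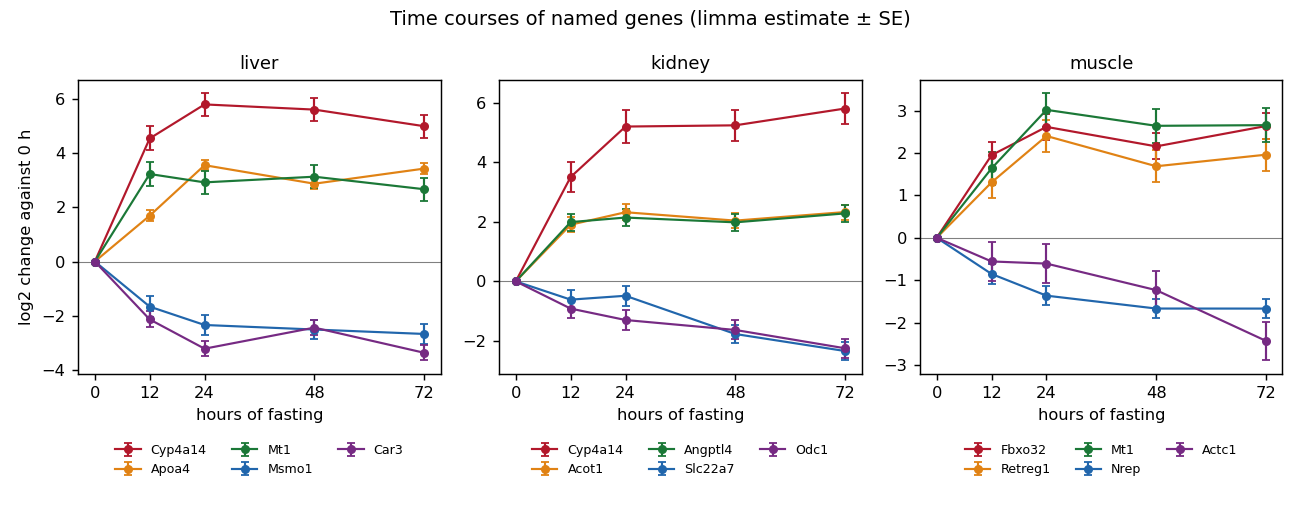
Log2 change against 0 h of 5 named genes in liver, kidney and muscle at each fasting time (hours); points are limma estimates, bars standard errors, and groups hold 4 or 5 mice. Cyp4a14 stood 5.79 above 0 h in liver and 5.20 in kidney at 24 h, and Fbxo32 2.62 in muscle.

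In the small intestine 29 genes rose and 16 fell after 24 h (5 mice each). Mt1 (2.67 ± 0.48) rose most, followed by the gluconeogenic enzyme Pck1 (1.53 ± 0.33), the mitochondrial thiolase Acaa2 (1.45 ± 0.17), the prostaglandin dehydrogenase Hpgd (1.38 ± 0.26) and the kinase Sgk1 (1.31 ± 0.28). The desaturase Scd2 (-1.33 ± 0.25), Gsdmc (-1.26 ± 0.16), the glutathione peroxidase Gpx2 (-1.13 ± 0.19), the chemokine Ccl24 (-0.91 ± 0.14) and the deiodinase Dio1 (-0.78 ± 0.14) fell most. Of 21 fatty acid oxidation genes 2 rose, Acaa2 and Hsd17b4 (0.66 ± 0.11), and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.31 (camera, adjusted p = 7.7e-15, and 0.03 with an estimated correlation). Of 18 cholesterol synthesis genes 2 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 1.31e-09, and 0.0381 with an estimated correlation). Slide family as a term ended the calls of Mt1 (2.33), Pck1 (1.55), Hpgd (1.35) and Sgk1 (1.42). Leaving out mouse 1, 3 or 6 at 0 h or mouse 20 or 21 at 24 h gave 18 to 29 changed genes in place of 45, and leaving out mouse 5 at 0 h gave 133. Calls were lost for Pck1 without mouse 1, 2, 3 or 6 at 0 h or mouse 18, 20 or 21 at 24 h (1.28 to 1.63) and Sgk1 without mouse 1 or 3 at 0 h or mouse 17, 18, 20 or 21 at 24 h (1.16 to 1.34). They were also lost for Hpgd without mouse 1 or 3 at 0 h (1.33) and Scd2 without mouse 1 at 0 h (-1.26).

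After 72 h 100 genes rose and 159 fell in intestine (5 mice each), 29 and 11 of them by at least 2-fold. Time and slide family were nearly confounded here, since 4 of 5 arrays at 0 h and 0 of 5 at 72 h came from slide family 1, and with slide family as a term 21 genes passed (16 higher, 5 lower) in place of 259. Mt1 (2.48 ± 0.48), the cytochrome Cyp3a44 (2.31 ± 0.52), the glutathione transferase Gsta2 (2.00 ± 0.36), Tm4sf4 (1.87 ± 0.20) and the aldo-keto reductase Akr1b8 (1.70 ± 0.23) rose most. The antibacterial lectin Reg3g (-1.90 ± 0.39), Hbb-b2 (-1.88 ± 0.24), Gpx2 (-1.38 ± 0.19), the nucleic acid sensor Zbp1 (-1.35 ± 0.22) and Hba-a1 (-1.30 ± 0.21) fell most. In fatty acid oxidation 7 of 21 genes rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.38 (adjusted p = 2.44e-13, and 0.03 with an estimated correlation). Acaa2 (1.44 ± 0.17), Acadl (0.73 ± 0.13) and Slc25a20 (0.62 ± 0.10), the carnitine carrier of mitochondria, were among them. Of 20 genes of the glucocorticoid response, 4 rose and 0 fell (median 0.40, adjusted p = 1.07e-08; adjusted p = 0.0564 with an estimated correlation). Sgk1 (1.64 ± 0.28), Tsc22d3 (0.98 ± 0.20) and Fkbp5 (0.66 ± 0.10) were among them. Pck1 (1.53 ± 0.33) and G6pc (1.29 ± 0.27), the last enzyme of glucose release, were higher. Of the genes named here, Tm4sf4, Akr1b8, Acaa2, Hbb-b2 and Gpx2 kept their call with slide family as a term. The others kept their direction with an adjusted p of 0.0517 (Sgk1) to 0.383 (Cyp3a44), and both lists kept their call at the preset correlation. Without 1 array calls were lost for Cyp3a44 without mouse 1 or 6 at 0 h or mouse 38 at 72 h (1.97 to 2.23) and Pck1 without mouse 1 at 0 h or mouse 38 or 40 at 72 h (1.34 to 1.42).

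Immune genes were lower in intestine at 72 h, in the comparison nearly confounded with slide family. Of 19 genes of the interferon response 5 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.39 (adjusted p = 1.07e-07; adjusted p = 0.392 with an estimated correlation). Igtp (-0.94 ± 0.21), Psmb10 (-0.74 ± 0.11), Psmb8 (-0.61 ± 0.14) and Psmb9 (-0.60 ± 0.13) were among them. Of 16 markers of macrophages and antigen presentation 4 fell and 0 rose (adjusted p = 3.32e-07; adjusted p = 0.0564 with an estimated correlation). H2-Ab1 (-1.01 ± 0.20) and Cd74 (-0.97 ± 0.21) were lowest. Cell cycle genes had 3 of 33 lower and 0 higher (16 and 0 adjusted over the list alone; adjusted p = 3.23e-07; adjusted p = 0.392 with an estimated correlation). Of 23 extracellular matrix genes 6 fell and 1 rose (adjusted p = 0.00484; adjusted p = 0.266 with an estimated correlation). Sparc (-0.74 ± 0.13) was lower and Col3a1 (0.57 ± 0.11) higher. Of the 8 genes named here, 0 kept their call with slide family as a term (adjusted p = 0.0539 for Psmb10 to 0.383 for Igtp). Their directions stayed and the 4 lists kept their call, with the interferon median at -0.14. Without 1 array calls were lost for Igtp without mouse 1, 2 or 3 at 0 h or mouse 36 or 40 at 72 h (-0.90 to -0.87) and Psmb8 without mouse 1, 2 or 3 at 0 h or mouse 36, 38 or 40 at 72 h (-0.60 to -0.54). They were also lost for Psmb9 without mouse 3 at 0 h or mouse 40 at 72 h (-0.54 to -0.52) and Cd74 without mouse 1 or 2 at 0 h or mouse 36 or 40 at 72 h (-0.91 to -0.83). Markers of the exocrine pancreas, an organ that lies against the gut, had medians of 2.09, 1.56, 3.00 and 2.30 at 12, 24, 48 and 72 h, and 0 of the 13 markers passed the test in limma at any time. Hepatocyte markers had a median of 0.80 at 72 h (adjusted p = 0.000199; adjusted p = 0.511 with an estimated correlation), and the sign of the hepatocyte list turned with the arrays scaled to 1 spread (median -0.66, adjusted p = 0.693).

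At 12 h 4 genes rose and 9 fell in intestine, and at 48 h 73 rose and 198 fell. Between 24 and 72 h limma called 0 genes higher and 1 lower. 1 of 18 cholesterol synthesis genes fell at 12 h (9 adjusted over the list alone; adjusted p = 2.26e-07; adjusted p = 0.0564 with an estimated correlation) and 6 at 48 h (11 adjusted over the list alone; adjusted p = 8.81e-07; adjusted p = 0.0649 with an estimated correlation). The counts in this tissue depended on single arrays. At 72 h they were 116 to 143 without mouse 1, 2, 3 or 6 at 0 h or mouse 36, 38 or 40 at 72 h and 923 without mouse 5 at 0 h, in place of 259. At 48 h they were 41 to 141 without mouse 1, 2, 3 or 6 at 0 h or mouse 32, 54 or 55 at 48 h, 551 without mouse 30 at 48 h and 1558 without mouse 5 at 0 h, in place of 271. At 12 h they were 2 to 7 without mouse 1, 2, 3 or 6 at 0 h or mouse 10, 11, 12 or 13 at 12 h and 509 without mouse 5 at 0 h, in place of 13. With slide family as a term 76 genes passed at 48 h in place of 271.

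In the kidney Cyp4a14 (5.20 ± 0.55) and Cyp4a10 (3.10 ± 0.33) rose most after 24 h (4 fasted and 5 fed mice; adjusted p = 2.42e-05 and 2.42e-05), followed by the thioesterase Acot1 (2.32 ± 0.27), the lipase inhibitor Angptl4 (2.14 ± 0.30) and the spot for Fasn (1.85 ± 0.25). The creatine-synthesis enzyme Gatm (-1.64 ± 0.30), the dipeptidase Cndp2 (-1.61 ± 0.30), Acot11 (-1.46 ± 0.18) and Akr1c21 (-1.34 ± 0.18) fell most. The polyamine enzyme Odc1 (-1.30 ± 0.34) followed at the threshold. In total 130 genes rose and 92 fell, 22 and 9 by at least 2-fold. Of 21 fatty acid oxidation genes 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.56 (camera, adjusted p = 3.33e-21; adjusted p = 0.0564 with an estimated correlation). Acaa1a (1.52 ± 0.27), Ehhadh (1.42 ± 0.17), Cpt2 (1.08 ± 0.14) and Cpt1a (0.40 ± 0.080) were among them. Of 18 PPAR alpha targets 8 rose and 0 fell (adjusted p = 1.01e-11; adjusted p = 0.0564 with an estimated correlation), with Vnn1 (1.75 ± 0.22) beside those already named. Pck1 (1.60 ± 0.19), Fbp2 (0.53 ± 0.11) and Pcx (0.52 ± 0.10) rose among 13 gluconeogenesis genes (adjusted p = 0.000857; adjusted p = 0.261 with an estimated correlation), a list whose call ended with median centring (median -0.25, adjusted p = 0.682).

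Folding factors of the endoplasmic reticulum fell in kidney at 24 h. Of 18 endoplasmic reticulum chaperones 6 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.28 (adjusted p = 3.86e-11; adjusted p = 0.0649 with an estimated correlation): Hspa5 (-0.98 ± 0.18), Hsp90b1 (-0.77 ± 0.14), Calr (-0.75 ± 0.14), Pdia3 (-0.70 ± 0.14), Dnajb11 (-0.57 ± 0.093) and Canx (-0.29 ± 0.056). Of the enzymes of fatty acid and triglyceride synthesis other than Fasn, Gpam (1.04 ± 0.19) rose, Acly (-0.34 ± 0.071) fell and the others did not pass the test, with the call lost for Acly without mouse 18 at 24 h (-0.28). Cholesterol synthesis genes had 3 of 18 lower and 1 higher (adjusted p = 0.00568; adjusted p = 0.184 with an estimated correlation). Idi1 (-1.05 ± 0.15) was lowest. Without mouse 2 or 6 at 0 h or mouse 18 or 19 at 24 h the count was 122 to 141 in place of 222, and with slide family as a term it was 134. The family term ended the calls of Cpt1a (0.39), Fbp2 (0.51) and Pdia3 (-0.64).

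At 72 h 473 genes rose and 589 fell in kidney (5 mice each), 41 and 35 by at least 2-fold. Cyp4a14 (5.80 ± 0.52), Cyp4a10 (3.33 ± 0.31), Acot1 (2.33 ± 0.25), the tyrosine-breakdown enzyme Hpd (2.28 ± 0.36) and Angptl4 (2.28 ± 0.28) rose most. The medium-chain acyl-CoA ligase Acsm3 (-2.58 ± 0.21), the organic anion carrier Slc22a7 (-2.34 ± 0.31), Odc1 (-2.25 ± 0.32), Cndp2 (-2.22 ± 0.28) and Inmt (-2.12 ± 0.25) fell most. Of 31 ribosomal protein genes 21 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.39 (adjusted p = 6.76e-23; adjusted p = 0.0649 with an estimated correlation). Rpl5 (0.67 ± 0.11) and Rps28 (0.65 ± 0.094) were among them. Fatty acid oxidation had 11 of 21 genes higher and 0 lower (median 0.43, adjusted p = 3.4e-12; adjusted p = 0.145 with an estimated correlation). In the urea cycle and amino acid breakdown 6 of 27 genes rose and 1 fell (adjusted p = 0.000241; adjusted p = 0.495 with an estimated correlation), with Gldc (2.15 ± 0.20) and Glud1 (1.17 ± 0.20) beside Hpd. Pck1 (1.88 ± 0.18), Fbp2 (0.48 ± 0.10) and Slc25a25 (0.69 ± 0.16) rose among 13 gluconeogenesis genes, of which 4 rose and 0 fell (adjusted p = 0.000448; adjusted p = 0.219 with an estimated correlation). With the arrays scaled to 1 spread the calls of gluconeogenesis (median 0.13, adjusted p = 0.136) and of the urea cycle and amino acid breakdown (median 0.08, adjusted p = 0.058) ended.

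Single genes of renal transport changed in both directions in kidney at 72 h. Of 26 genes of renal solute transport 6 fell and 3 rose (median -0.08, adjusted p = 0.204), and the list median turned to 0.06 with median centring. Slc22a7, the amino acid carrier Slc7a13 (-1.84 ± 0.31) and the glucose carrier Slc5a2 (-0.85 ± 0.13) fell, and the sulphate carrier Slc13a1 (0.71 ± 0.19) rose. The call was lost for Slc13a1 without mouse 38 at 72 h (0.64). Of 20 glucocorticoid response genes 6 rose and 0 fell (adjusted p = 2.99e-06; adjusted p = 0.194 with an estimated correlation). Sgk1 (1.45 ± 0.28), Tsc22d3 (0.92 ± 0.20) and Klf15 (0.54 ± 0.10) were among them. Of 16 markers of macrophages and antigen presentation 5 fell and 0 rose (adjusted p = 0.00483; adjusted p = 0.388 with an estimated correlation). H2-Aa (-1.30 ± 0.24) and Cd74 (-1.29 ± 0.21) were lowest. With the arrays scaled to 1 spread the call of macrophage and antigen presentation ended (median -0.11, adjusted p = 0.0721).

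At 12 h 22 genes rose and 4 fell in kidney, and at 48 h 173 rose and 241 fell. Fatty acid oxidation had 4 of 21 genes higher at 12 h (17 adjusted over the list alone; median 0.48, adjusted p = 4.71e-29, and 0.03 with an estimated correlation), with Cyp4a14 (3.50 ± 0.52) and Cyp4a10 (2.36 ± 0.31) among the PPAR alpha targets. Hepatocyte markers had a median of -0.61 at 12 h (adjusted p = 0.0307; adjusted p = 0.702 with an estimated correlation), which ended as a call with the arrays scaled to 1 spread (median -1.30, adjusted p = 0.171), and 0 of 11 passed in limma. Between 24 and 72 h 60 genes rose and 154 fell, with Acsm3 (-2.27 ± 0.22) and Slc22a7 (-1.85 ± 0.33) lower. The count at 12 h was 15 without mouse 12, 17 without mouse 11 and 120 without mouse 10 at 12 h, in place of 26. At 48 h it was 257 to 273 without mouse 2 at 0 h or mouse 31 or 32 at 48 h, in place of 414. Between 72 and 24 h it was 70 to 132 without mouse 19 or 20 at 24 h or mouse 36, 38 or 40 at 72 h and 432 without mouse 33 at 72 h, in place of 214.

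In calf muscle, 484 genes rose and 402 fell after 24 h (5 mice each), 66 and 7 of them by at least 2-fold. Mt1 (3.02 ± 0.40), the ubiquitin ligase of muscle atrophy Fbxo32 (2.62 ± 0.31), the receptor for removal of endoplasmic reticulum Retreg1 (2.40 ± 0.37), Tmem140 (2.20 ± 0.28) and the transcription factor Cebpd (2.19 ± 0.27) rose most (adjusted p = 1.31e-05 for Fbxo32). Fbxo32 (gene identifier 67731, chromosome 15) went from a log2 ratio to the reference of -0.41 ± 0.17 (SD) to 2.21 ± 0.06 (SD). The clock output gene Dbp (-1.59 ± 0.15), Nrep (-1.36 ± 0.23), the calmodulin gene Calm2 (-1.32 ± 0.22), the polyamine enzyme Amd2 (-1.21 ± 0.25) and Acly (-1.13 ± 0.23) fell most. The clock time of killing is not given, so that the change of Dbp cannot be separated from time of day. The direction of Calm2 turned under 1 alternative, to 0.04 with the arrays scaled to 1 spread.

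Genes of muscle breakdown rose together at 24 h. Of 26 muscle atrophy genes 22 rose and 1, the growth inhibitor Mstn (-0.43 ± 0.092), fell, with a median of 0.85 (camera, adjusted p = 3.43e-22; adjusted p = 0.0649 with an estimated correlation). Gadd45a (2.07 ± 0.29), Cdkn1a (1.92 ± 0.25), Eif4ebp1 (1.68 ± 0.26) and Bnip3 (1.39 ± 0.24) were among them. Of 30 proteasome subunits 12 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.39, adjusted p = 3.49e-11; adjusted p = 0.397 with an estimated correlation), including Psmc3 (1.36 ± 0.17). Of 19 glucocorticoid response genes 10 rose, such as Glul (1.67 ± 0.20) and Klf9 (0.89 ± 0.15), and 1, Sgk1 (-0.45 ± 0.10), fell (adjusted p = 1.26e-08; adjusted p = 0.0594 with an estimated correlation). Of 20 FoxO and insulin-repressed genes 8 rose and 1 fell (adjusted p = 0.000215; adjusted p = 0.172 with an estimated correlation). Sesn1 (2.07 ± 0.28), Foxo1 (0.84 ± 0.13) and Txnip (0.80 ± 0.17) were higher and Tob1 (-0.76 ± 0.16) lower. In fatty acid and triglyceride synthesis 7 of 22 genes fell and 0 rose (adjusted p = 2.8e-05; adjusted p = 0.194 with an estimated correlation). Scd2 (-1.10 ± 0.18), Slc25a1 (-0.89 ± 0.16) and Fasn (-0.65 ± 0.20) were lower. The call of fatty acid and triglyceride synthesis ended with the arrays scaled to 1 spread (median -0.11, adjusted p = 0.058). The fatty acid uptake gene Cd36 (0.91 ± 0.15) rose. The call was lost for Fasn without mouse 1, 3, 5 or 6 at 0 h or mouse 18, 19, 20 or 21 at 24 h (-0.69 to -0.53).

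At 72 h 1052 genes rose and 1415 fell in muscle (5 mice each), 72 and 78 by at least 2-fold. Mt1 (2.66 ± 0.40), Fbxo32 (2.64 ± 0.31), the inhibitor of translation Eif4ebp1 (2.23 ± 0.26), Retreg1 (1.96 ± 0.37) and Sesn1 (1.87 ± 0.28) rose most, and the cardiac actin Actc1 (-2.43 ± 0.46), Hbb-b2 (-1.99 ± 0.23), Nrep (-1.67 ± 0.23), Amd2 (-1.66 ± 0.25) and the antigen presentation gene H2-Aa (-1.60 ± 0.29) fell most. Proteasome subunits had 24 of 30 genes higher and 0 lower (27 and 0 adjusted over the list alone; median 0.69, adjusted p = 6.4e-17; adjusted p = 0.266 with an estimated correlation). Psmd4 (1.31 ± 0.17), Psma7 (1.21 ± 0.19) and Psmd2 (1.07 ± 0.10) were highest. Muscle atrophy genes had 22 of 26 higher and 0 lower (median 0.89, adjusted p = 8.2e-18; adjusted p = 0.106 with an estimated correlation). Of 24 genes of autophagy and the lysosome 9 rose, including Bnip3 (1.60 ± 0.24), Ctsl (1.18 ± 0.26) and Map1lc3b (0.90 ± 0.14), and 2 fell (adjusted p = 0.00328; adjusted p = 0.435 with an estimated correlation). Of 19 glucocorticoid response genes 11 rose and 0 fell (adjusted p = 4.74e-09; adjusted p = 0.0564 with an estimated correlation).

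Lists of oxidative phosphorylation, glycolysis and extracellular matrix genes were lower in muscle at 72 h. Of 42 genes of oxidative phosphorylation 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.000168; adjusted p = 0.556 with an estimated correlation), and the call of oxidative phosphorylation ended with print-tip loess (median -0.16, adjusted p = 0.0812). Of 17 glycolysis genes 7 fell, with Ldha (-1.26 ± 0.18), Pgam2 (-1.10 ± 0.19) and Eno3 (-1.04 ± 0.22) lowest, and 1, Hk1 (0.52 ± 0.11), rose (adjusted p = 0.0235; adjusted p = 0.487 with an estimated correlation). The call of glycolysis ended with slide family as a term (median -0.15, adjusted p = 0.0544). Of 24 extracellular matrix genes 11 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.000445; adjusted p = 0.266 with an estimated correlation). Sparc (-1.53 ± 0.17), Col1a2 (-0.97 ± 0.25) and Col6a1 (-0.89 ± 0.16) were lowest. In mitochondrial and peroxisomal fatty acid oxidation 7 of 21 genes rose and 5 fell (median 0.09, adjusted p = 0.138), the median being -0.05 with median centring. Acadl (0.94 ± 0.17) and Eci2 (0.87 ± 0.13) were higher. The thiolase Acaa2 (-0.46 ± 0.13) was lower, and its direction turned to 0.42 with the arrays scaled to 1 spread. Genes of other organs moved beside these lists. Renal solute transport had 6 of 22 genes lower and 0 higher (median -0.55, adjusted p = 0.00025; adjusted p = 0.615 with an estimated correlation), a call that ended with the arrays scaled to 1 spread (median -0.03, adjusted p = 0.981). The hepatocyte list had a median of -0.84 (adjusted p = 0.0652), which turned to 3.46 with the arrays scaled to 1 spread and to 0.21 with the arrays scaled to 1 slope.

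At 12 h 65 genes rose and 8 fell in muscle, and at 48 h 424 rose and 223 fell. With the arrays scaled to 1 slope the excess of rises ended at 12 h (178 and 222) and shrank at 48 h (591 and 574). With 1 spread it ended at both (16 and 26, 623 and 852). Muscle atrophy genes had 4 of 26 higher at 12 h (16 adjusted over the list alone; adjusted p = 6.5e-14; adjusted p = 0.176 with an estimated correlation), with Fbxo32 (1.95 ± 0.31). At 48 h 20 of 26 muscle atrophy genes (adjusted p = 3.57e-20; adjusted p = 0.0824 with an estimated correlation) and 22 of 30 proteasome subunits rose (adjusted p = 6e-23; adjusted p = 0.176 with an estimated correlation). Between 24 and 72 h 154 genes rose and 113 fell. The counts moved by more than 1.5 times without some arrays: at 24 h to 469 to 557 without mouse 1, 3 or 5 at 0 h or mouse 18 or 19 at 24 h and to 1401 without mouse 2 at 0 h, in place of 886. At 72 h the count was 1620 without mouse 36 at 72 h, in place of 2467. At 12 h it was 39 to 47 without mouse 5 at 0 h or mouse 12 or 14 at 12 h, 278 without mouse 10 at 12 h and 310 without mouse 2 at 0 h, in place of 73. At 48 h it was 305 to 408 without mouse 1, 3 or 5 at 0 h or mouse 30 or 31 at 48 h and 1069 without mouse 32 at 48 h, in place of 647. Between 72 and 24 h it was 137 without mouse 19 at 24 h, 173 without mouse 21 at 24 h and 169 without mouse 35 at 72 h, in place of 267.

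In brain few genes passed the test at any time. At 72 h 15 rose and 22 fell (5 mice each), 0 and 2 of them by at least 2-fold. The cell cycle inhibitor Cdkn1a (0.91 ± 0.16), the kinase Sgk1 (0.67 ± 0.12), the transcription factor Dlx1 (0.63 ± 0.11), the glycolytic enzyme Aldoc (0.57 ± 0.12) and the non-coding RNA Zfas1 (0.53 ± 0.068) rose most. Hbb-b2 (-2.35 ± 0.20), Hba-a1 (-2.12 ± 0.18), the carbonic anhydrase Car2 (-0.80 ± 0.14), the haem synthesis gene Alas2 (-0.68 ± 0.074) and the small heat shock protein Cryab (-0.67 ± 0.10) fell most. Of 18 cholesterol synthesis genes 2 fell, Msmo1 (-0.61 ± 0.12) and Idi1 (-0.46 ± 0.073), and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.17 (camera, adjusted p = 3.49e-11, and 0.03 with an estimated correlation). At 12, 24 and 48 h the same list had 5, 7 and 5 genes lower adjusted over the list alone (adjusted p = 0.0449, 0.03 and 0.0564 with an estimated correlation). Of 20 glucocorticoid response genes 2, Cdkn1a and Sgk1, rose and 0 fell at 72 h (8 and 0 adjusted over the list alone; adjusted p = 1.88e-08; adjusted p = 0.0564 with an estimated correlation).

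At 24 h Mfsd2a (0.51 ± 0.061), which carries docosahexaenoic acid into the brain, rose in brain, and no other gene passed (4 fasted and 5 fed mice). At 12 h 0 genes passed, and at 48 h 1 rose and 0 fell. In limma 207, 358 and 332 genes had an unadjusted p under 0.05 at 12, 24 and 48 h, fewer than chance would give among 11354. Glucocorticoid response genes had 7, 4 and 8 members higher adjusted over the list alone at 12, 24 and 48 h (adjusted p = 0.03, 0.0449 and 0.03 with an estimated correlation). Hepatocyte markers, which brain cells hardly express, had medians of -0.57, -0.49, -0.93 and -0.81 at 12, 24, 48 and 72 h, with 0 of 11 passing in limma at 72 h, and the hepatocyte median at 72 h turned to 0.26 with the arrays scaled to 1 spread. Between 24 and 72 h limma called 0 genes higher and 4 lower. Without mouse 1 or 2 at 0 h or mouse 36 at 72 h the count at 72 h was 22 or 23 in place of 37. At 72 h calls were lost for Aldoc without mouse 1, 2, 5 or 6 at 0 h or mouse 35, 36, 38 or 40 at 72 h (0.52 to 0.59) and Msmo1 without mouse 1, 5 or 6 at 0 h or mouse 36, 38 or 40 at 72 h (-0.60 to -0.57). The gene called at 48 h was lost without any 1 of mice 1, 2, 3 and 6 at 0 h and mice 30, 31, 54 and 55 at 48 h.

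**Figure D3:**
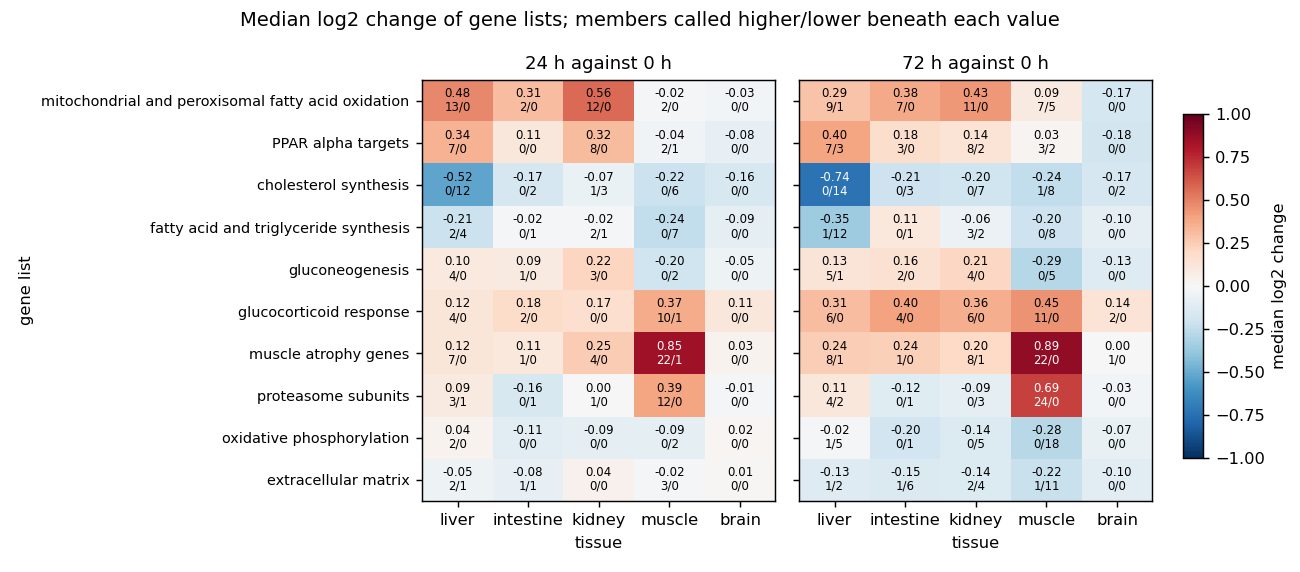
Median log2 change of 10 gene lists in 5 tissues at 24 and 72 h against 0 h, as colour and printed value, with the number of members called higher and lower beneath (limma, adjusted p under 0.05). The fatty acid oxidation list had medians of 0.48 in liver, 0.31 in intestine and 0.56 in kidney at 24 h, and muscle atrophy genes 0.85 in muscle.

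The responses of the organs differed. Of 9702 genes tested in all 5 tissues, the change at 24 h differed between tissues for 1001 (10.3%) and the change at 72 h for 2844 by the F test of limma, and with the mouse as a block for 1092 and 3034. Liver and muscle differed in 734 genes at 24 h and 1615 at 72 h, and intestine and brain in 4 and 128. Several named genes had opposite calls. At 24 h Inmt fell in liver (-2.26) and kidney (-1.03) and rose in muscle (0.92). Odc1 rose in muscle (1.36), and its fall in kidney (-1.30) was not firm (limma adjusted p = 0.05, at the threshold). At 72 h Gsta2 rose in intestine (2.00) and kidney (1.94) and fell in liver (-0.69). Each difference passed its test. The Fasn spot rose in liver and kidney and fell in muscle, where it went with the rest of its list. Calls at 24 h were lost for Inmt without mouse 1, 2, 3, 5 or 6 at 0 h or mouse 17, 18 or 19 at 24 h (-1.06 to -0.93) in kidney and Inmt without mouse 18 at 24 h (0.74) in muscle. Those of Inmt (-0.90) in kidney and Gsta2 (1.78) in intestine ended with slide family as a term.

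A small set of genes changed in 1 direction in all organs. At 72 h Hbb-b2, Hba-a1 and the isoprenoid enzyme Idi1 fell in all 5 tissues, 3 genes where independent calls would give 0.000256. Idi1 fell by 1.57 ± 0.21 in liver, 0.45 ± 0.088 in intestine, 1.36 ± 0.14 in kidney, 0.62 ± 0.19 in muscle and 0.46 ± 0.073 in brain. The intestine calls of Hba-a1 and of Idi1 (-0.33) ended with slide family as a term. The call in muscle was lost for Idi1 without mouse 1, 3 or 5 at 0 h or mouse 36 or 40 at 72 h (-0.58 to -0.52). In 4 tissues at 72 h 7 genes rose (0.0496 in independent calls) and 17 fell (0.14). Fkbp5 and Acadl rose in 4, and Cd74, Psmb8, Sparc, Msmo1 and Nsdhl fell in 4. All but Msmo1 and Nsdhl lost the intestine call with slide family as a term. The counts of 7 and 17 include such calls. At 24 h Nsdhl fell in 4 tissues and 2410006H16Rik and Epb41l4aos, which are transcripts of little-known function, rose in 4. Liver and kidney shared 51 genes that rose at 24 h where independent calls would give 3.12, and 170 that rose and 193 that fell at 72 h where they would give 42.0 and 61.3. The organs came from the same mice, so that the calls of 2 tissues were not fully independent.

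Transcripts of red blood cells were lower in every organ at 72 h. Hbb-b2 fell by 2.68 ± 0.20 in liver, 1.88 ± 0.24 in intestine, 1.99 ± 0.20 in kidney, 1.99 ± 0.23 in muscle and 2.35 ± 0.20 in brain (5 mice per group in each). Hba-a1 fell by 1.96, 1.30, 1.85, 1.57 and 2.12 in the same order. Alas2, the first enzyme of haem synthesis in red cell precursors, fell in liver (-1.12), kidney (-0.47), muscle (-0.41) and brain (-0.68), and its value in intestine was 0.03. The call in muscle was lost for Alas2 without mouse 1, 2, 3 or 5 at 0 h or mouse 35, 36 or 40 at 72 h (-0.43 to -0.35). At 48 h Hbb-b2 was lower in liver (-0.81). It did not pass the test in kidney (-0.65), brain (-0.58), intestine (-0.54) and muscle (-0.23). In intestine the call of Hba-a1 (-1.09) ended with slide family as a term.

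**Figure D4:**
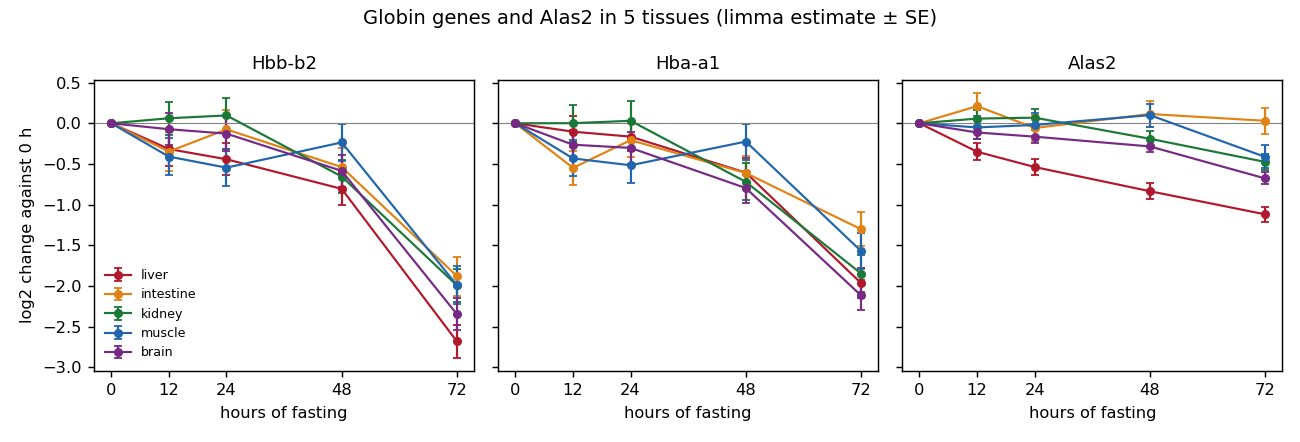
Log2 change against 0 h of Hbb-b2, Hba-a1 and Alas2 at each fasting time (hours) in 5 tissues; points are limma estimates, bars standard errors, and groups hold 4 or 5 mice. At 72 h Hbb-b2 lay between -2.68 in liver and -1.88 in intestine.

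With slide family as a term 223 of the 256 changes of named genes kept their direction and call. Of the 91 taken by the rule for the largest changes, 243 of 243 differences within a slide family had the direction of the full comparison, which that rule fixed by asking for arrays that did not overlap. Over all tissues and comparisons 387 of 1076 list tests were called, 182 up and 205 down, where shuffled mice gave a median of 203 calls and at most 304, and 12 remained with an estimated correlation. The 12 were cholesterol synthesis in liver at 24 h, in intestine at 24 h and in brain at 12, 24 and 72 h, gluconeogenesis in liver at 24 h, fatty acid oxidation in intestine at 24 and 72 h and in kidney at 12 h, and the glucocorticoid response in brain at 12, 24 and 48 h.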

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

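Of the tests in this part, those on haemoglobin, on the Fasn spot and on other splits of the mice were chosen only after the results had been seen. Those on genes of other organs in muscle and on differences between tissues were chosen before. In 7 of 162 groups of arrays of the named genes, 1 array lay far from the others of its group by Dixon's criterion, which chance alone meets in about 1 in 20 groups. In liver at 0 h, Hbb-b2 had a log2 ratio of 0.314 in mouse 6 and of 0.80 to 0.85 in the others. In intestine at 72 h, Hba-a1 stood at -2.79 in mouse 33 and at -2.56 to -2.47 in the others. In kidney at 0 h, mouse 3 had Acsm3 at 3.05 (others 2.48 to 2.65) and Inmt at 2.24 (others 2.36 to 2.40). In muscle at 0 h, Retreg1 stood at -1.39 in mouse 2 and at -0.56 to -0.25 in the others. In muscle at 24 h, Dbp stood at -1.46 in mouse 20 (others -1.01 to -0.85) and Acly at -1.17 in mouse 21 (others -0.58 to -0.34).

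The response to fasting differed between tissues for 1001 genes at 24 h and 2844 at 72 h (F test of limma). The opposite calls given next each passed the test of the difference. For Fasn the change in liver minus that in muscle was 3.07 at 24 h and 2.70 at 72 h, and kidney minus muscle was 2.50 and 2.74. For Inmt liver minus muscle was -3.18 and -2.15, and kidney minus muscle -1.95 and -3.33. For Odc1 kidney minus muscle was -2.66 at 24 h and -3.38 at 72 h, and liver minus kidney was 2.71 at 72 h. Sgk1 had an intestine minus muscle difference of 1.76 at 24 h. At 72 h, Acsm3 differed by 3.38 for liver minus kidney, Akr1b8 by 2.53 for intestine minus muscle, and Cyp3a44 by -3.21 for liver minus intestine. Gsta2 differed by -2.69 for liver minus intestine and -2.63 for liver minus kidney, and Tm4sf4 by 1.29 for liver minus muscle and 2.70 for intestine minus muscle. Spots to which the annotation gives no single gene symbol were outside the comparisons of genes. At 72 h 543 of 4117 such spots changed in liver, 19 of 4714 in intestine, 87 of 4013 in kidney, 341 of 3655 in muscle and 5 of 3618 in brain.

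Genes of other organs stood lower in muscle at 72 h: over 8 lists of genes of liver, gut, kidney, pancreas and brain, the median of the list medians was -0.66, against -0.532 for genes matched on their ratio at 0 h. An array-wide width of the log ratios was tested by scaling each array to 1 slope. The genes with the lowest ratios at 0 h then had a median of -0.215, from -0.306 before, and between -0.256 and -0.178 without 1 array (jackknife standard error 0.0697). With the lowest genes taken by the mean ratio over all muscle arrays, a choice made after the results had been seen, the median was -0.249 (jackknife standard error 0.0713), from -0.34 before. Both medians lay below -0.2 and met the bound set in advance against the width, but by less than 1 standard error. The excess over matched genes was to test RNA of other organs at 0 h and lower transcripts in fasted muscle. It was -0.193, and -0.168 after that scaling, between the bounds. Both would lower the lists and matched genes can be of other organs, so it cannot decide. These explanations stay open. The most abundant marker of liver, Alb, had a log2 ratio of -4.69 ± 0.64 (SD) in muscle at 0 h and a change of -0.61 ± 0.61, and 10 of 12 hepatocyte markers were measured in muscle.

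Lower haemoglobin transcripts at 72 h in all 5 tissues remained after each array was scaled to 1 slope, with a smallest fall of Hbb-b2 of -2.02 and a highest adjusted p of 0.000283, which argues against an array-wide width of the log ratios. Less blood in the organs taken stays open. White cell genes had a median of -0.17 over 11 values, but 24 of 35 values lay near background and organs hold white cells of their own. The test, first read as excluding it, was therefore set aside after its value had been seen. Deviations of Hbb-b2 from the group means went together in the organs of a mouse, with a mean Pearson r over tissue pairs of 0.329 and a mean Spearman rho of 0.305 in 25 mice (one-sided permutation p = 4e-04 for each, 10000 shuffles). The mean r was 0.19 without the 2 mice farthest from the median. This was the single relation computed for these genes. Fewer young red cells in the whole mouse may account for it, as a hypothesis, and a difference in blood between mice, which could give the same relation, was not excluded.

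The Fasn spot stood higher in fasted liver and kidney, whereas 1 of 20 other genes of fatty acid and triglyceride synthesis rose at 24 h in either tissue, which argues against higher fatty acid synthesis genes as a group (1 at most). Fat tissue in the kidney samples was argued against by the adipocyte list, whose median change was 0.151 at 24 h against 1.85 for the spot, with Adipoq at 0.53 and Fabp4 at 0.30 not passing and Ucp1 at 0.51 passing. That the spot reads another transcript stays open: within the times in liver its deviations had r = -0.373 (permutation p = 0.279, rho = -0.147 with p = 0.539, 0.113 without the 2 farthest arrays) with the other synthesis genes and r = 0.608 (permutation p = 0.00065, adjusted 0.0026, rho = 0.691 with p = 0.00126, 0.66 without those arrays) with genes of fatty acid oxidation. In kidney the values were 0.342 (permutation p = 0.198, adjusted 0.264, rho = 0.174 with p = 0.465, 0.0861 without the 2 farthest arrays) and 0.814 (permutation p = 0.00144, adjusted 0.00288, rho = 0.503 with p = 0.0271, 0.547 without them), 4 relations in all over 24 arrays each. A first version on pooled arrays (-0.714 and 0.846) was replaced after its values had been seen, because fed and fasted arrays fall in separate clusters.

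Other splits of the same mice into groups of the same sizes were counted for each result, 100 with the real one included, and 40 for the lists. Chance was taken as excluded where under 5 in 100 gave as many, the real one included, without adjustment over the 28 tests. The number is given where it was above 1. In liver the test was passed by the counts of 169 genes at 12 h (highest other split 57), 506 at 24 h (5), 814 at 48 h (4), 2189 at 72 h (2116) and 676 for 72 against 24 h (2142, 3 of 100). In intestine it was passed by 271 at 48 h (3130, 4 of 100) and 259 at 72 h (35). The splits do not speak to slide family, which was nearly confounded with 72 h there. Chance could not be excluded for 13 at 12 h (1228) and 45 at 24 h (1743), where 5 and 6 of 100 splits gave as many. In kidney the test was passed by 26 at 12 h (263, 3 of 100), 222 at 24 h (68), 414 at 48 h (17), 1062 at 72 h (172) and 214 for 72 against 24 h (752, 2 of 100). In muscle the same held for 73 at 12 h (587, 3 of 100), 886 at 24 h (1566, 2 of 100), 647 at 48 h (1508, 3 of 100), 2467 at 72 h (1439) and 267 for 72 against 24 h (6). In brain it held for 37 at 72 h (4). Counts of 1 at 24 h (5), 1 at 48 h (0) and 4 for 72 against 24 h (4) in brain and of 1 for 72 against 24 h in intestine (2) were equalled or passed in 3, 1, 2 and 2 of 100 splits, the real one included, and are too small to read more from. The 0 of limma in brain at 12 h (3474), with 207 genes at an unadjusted p under 0.05, cannot be tested this way, since any split reaches 0 (100 of 100). The differences between tissues, 1001 at 24 h (493) and 2844 at 72 h (1074), and the total of 387 list calls (304) passed the test too. The other shuffles gave a median of 203 list calls, so that chance is not excluded for any single list call.

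Splits that called several times the real count point to a structure of the samples. In intestine at 12, 24 and 48 h and in brain at 12 h the highest split was the most unequal or the next most unequal of the 100 in the spread of its arrays, and with the arrays scaled to 1 slope it called 78, 517, 1806 and 1694 genes. For 72 against 24 h it was the most unequal in liver and in kidney and called 1068 and 549. An unequal spread does not account for all of them, since the highest split in kidney at 12 h ranked 31 in spread and rose to 422 with that scaling. In muscle at 12 h it ranked 2, which goes with an unequal spread, but also rose, to 981. With slide family as a term the real counts in intestine at 24, 48 and 72 h were 28, 76 and 21, and that in muscle at 12 h, where 5 of 5 arrays came from slide family 1, was 26.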

How the results depend on the processing

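Scaling the arrays to 1 spread or to 1 slope, leaving out the arrays of low weight, and repeating the list tests under other settings were tests chosen after the data had been seen. Of the 28 counts, all stayed within 1.5 times their value without the filter on dim probes, with all probes of a gene, with genes detected in any tissue and with ranks in place of values, wherever these applied. The mouse as a block applied only to the differences between tissues (1092 and 3034 at 24 and 72 h). Quantile normalization of the mean signal leaves the log ratios as they are, so that it could move no count and no change. Of the 256 changes of named genes, 253 kept their direction and call with a normexp offset of 10 and 245 with print-tip loess. The count was 250 from the authors' value table and 251 with the arrays scaled to 1 slope. With slide family as a term 33 fell short of the threshold, with median centring 123, and with the arrays scaled to 1 spread 115. In 2526 values computed without 1 mouse, 88 fell short and 0 turned. With the arrays scaled to 1 spread, Calm2 in muscle at 24 h turned from -1.32 to 0.0372 and Acaa2 in muscle at 72 h from -0.46 to 0.42, and no other direction turned. Examples whose call held without any 1 array were preferred when genes were chosen for the text, so that these counts overstate how stable changed genes were in general. Of the 387 list calls, 12 remained with an estimated correlation. Slide family as a term kept 343 of them in the same direction, slope scaling 301, print-tip loess 352, median centring 306 and spread scaling 190. The direction turned for 70 with spread scaling, 5 with median centring, 2 with print-tip loess and 0 with slide family or slope scaling. The cause was not tested for any of these changes or for the counts below, except that a change of at least 2-fold is by construction a smaller set.

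In the counts that follow, the 5 comparisons are 12, 24, 48 and 72 h against 0 h and 72 against 24 h, in this order. Leaving out each array in turn gave 97 to 224, 387 to 470, 589 to 809, 1556 to 3134 and 389 to 1731 in liver, 2 to 509, 18 to 133, 41 to 1558, 116 to 923 and 1 to 1 in intestine. The ranges were 15 to 120, 122 to 228, 257 to 409, 777 to 1251 and 70 to 432 in kidney, 39 to 310, 469 to 1401, 305 to 1069, 1620 to 2808 and 137 to 317 in muscle, and 0 to 1, 1 to 3, 0 to 2, 22 to 41 and 4 to 5 in brain. For differences between tissues they were 747 to 1185 at 24 h and 2070 to 2935 at 72 h. Without background correction limma called 283 and 901 in liver at 12 and 24 h, and 24, 100, 505, 503 and 2 in intestine in the 5 comparisons. Limma called 87, 462, 733 and 380 in kidney at 12, 24 and 48 h and for 72 against 24 h, and 120 and 1352 in muscle at 12 and 48 h. Limma called 4, 10, 10, 69 and 10 in brain in the 5 comparisons. With a normexp offset of 10 limma called 0 (315 at an unadjusted p under 0.05) in brain at 48 h. With print-tip loess limma called 23, 98 and 458 in intestine at 12, 24 and 72 h. Genes higher and lower were 44 and 54 in intestine at 24 h in place of 29 and 16. With median centring limma called 15, 67, 75, 288 and 13 in liver in the 5 comparisons, and 2, 2, 10, 22 and 0 (219 at an unadjusted p under 0.05) in intestine in the 5 comparisons. Limma called 1, 7, 12, 96 and 128 in kidney in the 5 comparisons, and 1, 27, 2, 104 and 0 (410 at an unadjusted p under 0.05) in muscle in the 5 comparisons. Limma called 0 (388 at an unadjusted p under 0.05) and 5 in brain at 48 and 72 h. The response differed between tissues for 113 genes at 24 h and 692 at 72 h. Genes higher and lower were 14 and 1 in liver at 12 h in place of 99 and 70, and 35 and 40 in liver at 48 h in place of 467 and 347. They were 189 and 99 in liver at 72 h in place of 1008 and 1181, and 8 and 5 in liver for 72 against 24 h in place of 318 and 358. They were 0 and 2 in intestine at 12 h in place of 4 and 9, and 0 and 2 in intestine at 24 h in place of 29 and 16. They were 8 and 2 in intestine at 48 h in place of 73 and 198, and 18 and 4 in intestine at 72 h in place of 100 and 159. They were 1 and 0 in kidney at 12 h in place of 22 and 4, and 7 and 5 in kidney at 48 h in place of 173 and 241. They were 74 and 22 in kidney at 72 h in place of 473 and 589, and 126 and 2 in kidney for 72 against 24 h in place of 60 and 154. They were 0 and 1 in muscle at 12 h in place of 65 and 8, and 23 and 4 in muscle at 24 h in place of 484 and 402. They were 0 and 2 in muscle at 48 h in place of 424 and 223, and 67 and 37 in muscle at 72 h in place of 1052 and 1415. They were 1 and 4 in brain at 72 h in place of 15 and 22, and 1 and 4 in brain for 72 against 24 h in place of 0 and 4. From the authors' value table limma called 74 in intestine at 24 h, and 1 and 0 (332 at an unadjusted p under 0.05) in brain at 12 and 48 h. Genes higher and lower were 35 and 39 in intestine at 24 h in place of 29 and 16. With array quality weights limma called 275, 973, 1389, 3968 and 2900 in liver in the 5 comparisons, and 2483, 791, 4662, 2445 and 7 in intestine in the 5 comparisons. Limma called 327, 1866, 971, 2293 and 3631 in kidney in the 5 comparisons, and 2744, 4453, 3558 and 4279 in muscle at 12, 24, 48 and 72 h. Limma called 16, 31, 417 and 98 in brain at 24, 48 and 72 h and for 72 against 24 h. With all tissues in 1 model limma called 302 in liver at 12 h, and 506, 166, 1191, 832 and 39 in intestine in the 5 comparisons. Limma called 69 in kidney at 12 h, and 711, 1697, 1436 and 559 in muscle at 12, 24 and 48 h and for 72 against 24 h. Limma called 1, 3, 2 and 21 in brain at 12, 24 and 48 h and for 72 against 24 h. With a variance trend and robust estimation limma called 4 in intestine at 12 h, and 1, 2 and 2 in brain at 12, 24 and 48 h. With slide family as a term limma called 437 in liver for 72 against 24 h, and 28, 76 and 21 in intestine at 24, 48 and 72 h. Limma called 134, 272 and 131 in kidney at 24 and 48 h and for 72 against 24 h, and 26, 1515 and 1934 in muscle at 12, 24 and 48 h. Limma called 0 (375 at an unadjusted p under 0.05) in brain at 48 h. With a change of at least 2-fold as well limma called 30, 87, 93, 178 and 47 in liver in the 5 comparisons, and 3, 14, 20 and 40 in intestine at 12, 24, 48 and 72 h. Limma called 10, 31, 37, 76 and 13 in kidney in the 5 comparisons, and 21, 73, 52, 150 and 11 in muscle in the 5 comparisons. Limma called 0 (358 at an unadjusted p under 0.05), 0 (332 at an unadjusted p under 0.05), 2 and 2 in brain at 24, 48 and 72 h and for 72 against 24 h. With the arrays scaled to 1 spread limma called 499, 1261 and 96 in liver at 48 and 72 h and for 72 against 24 h, and 4, 4, 42, 54 and 0 (353 at an unadjusted p under 0.05) in intestine in the 5 comparisons. Limma called 1, 75, 41, 206 and 15 in kidney in the 5 comparisons, and 42, 1475 and 89 in muscle at 12 and 48 h and for 72 against 24 h. Limma called 3 and 19 in brain at 24 and 72 h. The 72 h response differed between tissues for 1834 genes. Genes higher and lower were 25 and 91 in liver at 12 h in place of 99 and 70, and 191 and 308 in liver at 48 h in place of 467 and 347. They were 27 and 69 in liver for 72 against 24 h in place of 318 and 358, and 0 and 4 in intestine at 12 h in place of 4 and 9. They were 1 and 3 in intestine at 24 h in place of 29 and 16, and 5 and 37 in intestine at 48 h in place of 73 and 198. They were 12 and 42 in intestine at 72 h in place of 100 and 159, and 1 and 0 in kidney at 12 h in place of 22 and 4. They were 7 and 8 in kidney for 72 against 24 h in place of 60 and 154, and 16 and 26 in muscle at 12 h in place of 65 and 8. They were 553 and 730 in muscle at 24 h in place of 484 and 402, and 623 and 852 in muscle at 48 h in place of 424 and 223. They were 4 and 2 in brain for 72 against 24 h in place of 0 and 4. With the arrays scaled to 1 slope limma called 400, 1333 and 1165 in muscle at 12, 24 and 48 h, and 3, 16 and 7 in brain at 12, 24 and 48 h. Genes higher and lower were 109 and 143 in liver at 12 h in place of 99 and 70, and 178 and 222 in muscle at 12 h in place of 65 and 8. They were 591 and 574 in muscle at 48 h in place of 424 and 223, and 1 and 2 in brain at 12 h in place of 0 and 0. They were 12 and 4 in brain at 24 h in place of 1 and 0, and 2 and 3 in brain for 72 against 24 h in place of 0 and 4. Without the arrays of low weight limma called 27 and 397 in intestine at 24 and 72 h, and 132, 349 and 379 in kidney at 12 and 24 h and for 72 against 24 h. Limma called 173 in muscle for 72 against 24 h.

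Median centring moved the median change of all genes to -0.155 in kidney and -0.109 in muscle at 24 h and to -0.111 at 48 h and -0.158 at 72 h in brain, and changes under it stand relative to those values. Signal over background limited what could be read: 53.32 to 65.43% of spots in the median array were above it, spots near background understate changes, and a rise from background is a lower limit.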

Other observations

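Among the fixed lists not described above, enzymes of detoxification changed in both directions in liver at 72 h. In all, 9 of 27 cytochrome P450 and conjugating enzymes rose and 10 fell (median 0.17, adjusted p = 0.351). Sult1a1 (1.67 ± 0.14) and Cyp3a13 (1.40 ± 0.16) were higher, and Ugt2b1 (-1.78 ± 0.23) and Cyp1a2 (-1.36 ± 0.27) lower. In the acute phase list 6 of 20 genes rose, among them Serpina3n (1.52 ± 0.20) and Fga (0.94 ± 0.24), and 2 fell (median 0.11, adjusted p = 0.0439; adjusted p = 0.704 with an estimated correlation). The call of the acute phase list ended, and its median turned, with the arrays scaled to 1 spread (median -0.64, adjusted p = 0.394) and to 1 slope (median -0.09, adjusted p = 0.585).

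In muscle the clock list had 2 of 13 genes higher and 2 lower at 24 h (median -0.04, adjusted p = 0.886), with the repressor Nfil3 (1.40 ± 0.16) higher and Dbp and Bhlhe40 (-0.49 ± 0.089) lower, and at 72 h Nfil3 stood at 1.34 and Dbp at -1.59. These cannot be separated from time of day. In intestine at 72 h the bile acid signal Fgf15 (0.92 ± 0.18) rose among 13 genes of bile acid synthesis and transport, of which 2 rose and 0 fell (median 0.47, adjusted p = 0.000103; adjusted p = 0.215 with an estimated correlation), a call that ended with the arrays scaled to 1 spread (median 0.11, adjusted p = 0.0611). In brain at 72 h markers of the hypothalamus and pituitary had a median of 0.23 with 0 of 8 passing over all genes in limma and 4 higher adjusted over the list alone (adjusted p = 4.54e-06; adjusted p = 0.144 with an estimated correlation). Feeding neuropeptides had a median of 0.13, with 0 of 19 passing over all genes in limma and 3 higher adjusted over the list alone (adjusted p = 4.7e-06; adjusted p = 0.156 with an estimated correlation).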
